A study of Mus musculus with 14 samples.

How the data were processed

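RNA was measured in mouse CD4+ T cells from 7 culture media with 2 libraries each, 14 in all. Per the labels' protocols, total RNA from sorted and cultured cells was made into libraries with a TruSeq kit. Per the submitters' processing notes, TopHat2 2.0.3, Cufflinks 1.3.0 and the mouse build mm9 were used, with no role given for each. The authors deposited FPKM values, which are scaled to transcript length and library size, in 2 tables: 1 holds replicate 1 of every medium and the other replicate 2. How the FPKM were scaled and whether the tables were scaled together is not given in the sources used here, nor are strand or the treatment of reads shared between genes. Levels of near-identical genes, such as those of the Ly6, Gbp and Tgtp families, and of overlapping genes are therefore uncertain.

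Each table held 30028 transcripts. Of these, 98.5% were named by the gene of their RefSeq accession in a mouse reference annotation of another build, which was used for names and transcript lengths alone; no coordinates were used. Another 241 were named by the symbol in the table, and 216 stood for themselves. FPKM of transcripts of 1 gene were summed, which gave 23298 genes. Genes with a mean of 1 FPKM or more in at least 1 medium were tested, 11511 in all. Values were log2(FPKM + 1).

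FPKM carry no read totals, but low values fell on whole-read steps. For genes at or under 0.15 FPKM, the value of 1 read was compared between each library and Th0 replicate 1, and between 62.3% and 70.0% of the compared genes lay within 1% of a ratio of up to 6 reads. The relative depth was 0.935 to 1.06 for replicate 1 libraries and 0.748 to 0.832 for replicate 2 libraries. It includes the total by which the authors scaled, and since only depth relative to that library follows from the steps, no counting interval is given.

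Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) over all 14 libraries, with 7 media that share 1 estimate of the spread and the table as a covariate, since the tables were deposited apart. This left 6 residual degrees of freedom and 3.37 prior ones. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called under 0.05. The 9 comparisons were the 6 other media against Th0, IL27_plus_TGF_beta against Th17_b and against iTreg, and Th17_b against Th17_23. A gene counted as specific to a medium when it was called higher than in each of the other 6 by a log2 change of 1 or more.

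Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They held helper lineage, regulatory and follicular genes, signalling targets, cytokines, chemokines and their receptors, cell cycle and metabolism genes, signs of RNA quality and stress, and markers of B, CD8, myeloid, dendritic, natural killer, erythroid, gamma-delta and NKT cells. All lists were tested in each comparison; all are reported for IL27_plus_TGF_beta against Th0, and for the other comparisons those that bear on them. Changes from Th0 were compared between media by correlation and covariance across genes, beside 100 simulations of unchanged media that share the Th0 libraries.

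The named genes follow a rule. It takes the 10 largest rises and 10 largest falls of IL27_plus_TGF_beta against Th0 and the 5 and 5 of each other comparison, among called genes with the same direction in both tables. It adds up to 4 members with the smallest p of each list, 25 lineage genes whatever their values, and the 10 specific genes of IL27_plus_TGF_beta with the largest margin. Genes without a symbol of their own, ribosomal protein genes and small RNAs are skipped among the largest changes and counted instead. The text gives a part of the genes that the rule takes; some of them, and 1 test made after the results were seen, are not reported here. The tests, lists, rule and alternatives were fixed before the data were examined, apart from the split of the Th0 libraries by table and the tests, lists and genes of the closing section.

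The alternatives were a fit without the table covariate, a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, scaling to 1 median, no trend, a fit of the compared media alone, the highest transcript of a gene in place of the sum, and leaving out each library of the compared media. Lists were also tested with an estimated correlation and with fry, and the similarity, as an alternative added after the results were seen, with the Th0 libraries split by table. The procedure was tested on simulated data for IL27_plus_TGF_beta against Th0, over 11511 genes. It recovered 38, 48, 50 and 50 of 50 genes each at log2 changes of 0.5, 1, 2 and 3, and called 13 of 11311 unchanged genes, 6.53% of the calls. This was 1 run, and the changed genes were drawn from those with a Th0 mean of log2(FPKM + 1) above 1. The recovery therefore does not cover genes that lie near 0 FPKM in Th0. A list of 20 genes shifted by a log2 of 0.7 was called, and 0 of 26 unshifted lists were. The simulated noise was independent between genes, so these lists do not test camera where members of a list are correlated. Far fewer genes were changed than were called in the data, so the share of false calls may differ there.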

Results

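Gene expression was measured by RNA sequencing in mouse CD4+ T cells. Naive cells from C57BL/6 mice were sorted by surface markers as CD4+ and CD25 negative, activated with plate-bound antibodies to CD3 and CD28, and collected after 3 days in 1 of 7 media. Each medium has 2 libraries, 14 in all. Th0 cells received antibodies to IFN-γ, IL-4 and IL-2 and no polarizing cytokine. IL27_plus_TGF_beta cells received the same 3 antibodies with IL-27 at 20 ng/ml and TGF-β at 2 ng/ml. By the additives named, these media differ in IL-27 and TGF-β alone. The labels give no dose for the antibodies in either medium, so equal neutralization is not shown. Th1 cells received IL-12, Th2 cells IL-4, and iTreg cells TGF-β at 20 ng/ml with IL-2. Th17_b cells received TGF-β at 2 ng/ml with IL-6, and Th17_23 cells IL-1β, IL-6 and IL-23 with antibodies to TGF-β. Per the labels, antibodies to IL-2 were also in the Th17_b and Th17_23 media and are not named for Th1, Th2 and iTreg, antibodies to IFN-γ were in every medium but that of Th1, and Th1 cells received an antibody to IL-4. The series title names the helper subsets and the IL-27 and TGF-β treatment, and the comparisons ask how each medium changed the cells from Th0 and how the IL-27 and TGF-β cells stand to the TGF-β subsets.

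The values are FPKM for 30028 transcripts, summed to 23298 genes, of which 11511 were tested. The smallest FPKM values fall on steps worth whole reads, and by these steps the libraries held between 0.748 and 1.06 times the depth of the first Th0 library, as the authors' scaling counted it. Every library listed between 10306 and 10667 genes at 1 FPKM or more. Levels below are FPKM as mean ± SD (n = 2), and changes are log2 changes ± SE on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was called at an adjusted p under 0.05 in limma. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure the spread between these samples only.

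The lineage genes separated the media. Tbx21, which encodes T-bet, stood at 32.4 ± 0.146 FPKM in Th1 and 0.423 ± 0.255 in Th0. Gata3, the Th2 master regulator, reached 105 ± 16.8 in Th2. Foxp3, the regulatory T cell factor, reached 100.3 ± 5.46 in iTreg and at most 1.28 on average in any other medium. Il17a, the cytokine of Th17 cells, stood at 367 ± 115 in Th17_b and 114 ± 32.7 in Th17_23, and between 0.0370 and 0.149 on average elsewhere. Across genes, replicates of 1 medium correlated at 0.985 to 0.992 and libraries of different media at 0.867 to 0.979; genes are not independent replicates. The first 3 principal components held 31.8%, 28.5% and 13.5% of the variance.

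**Figure D1:**
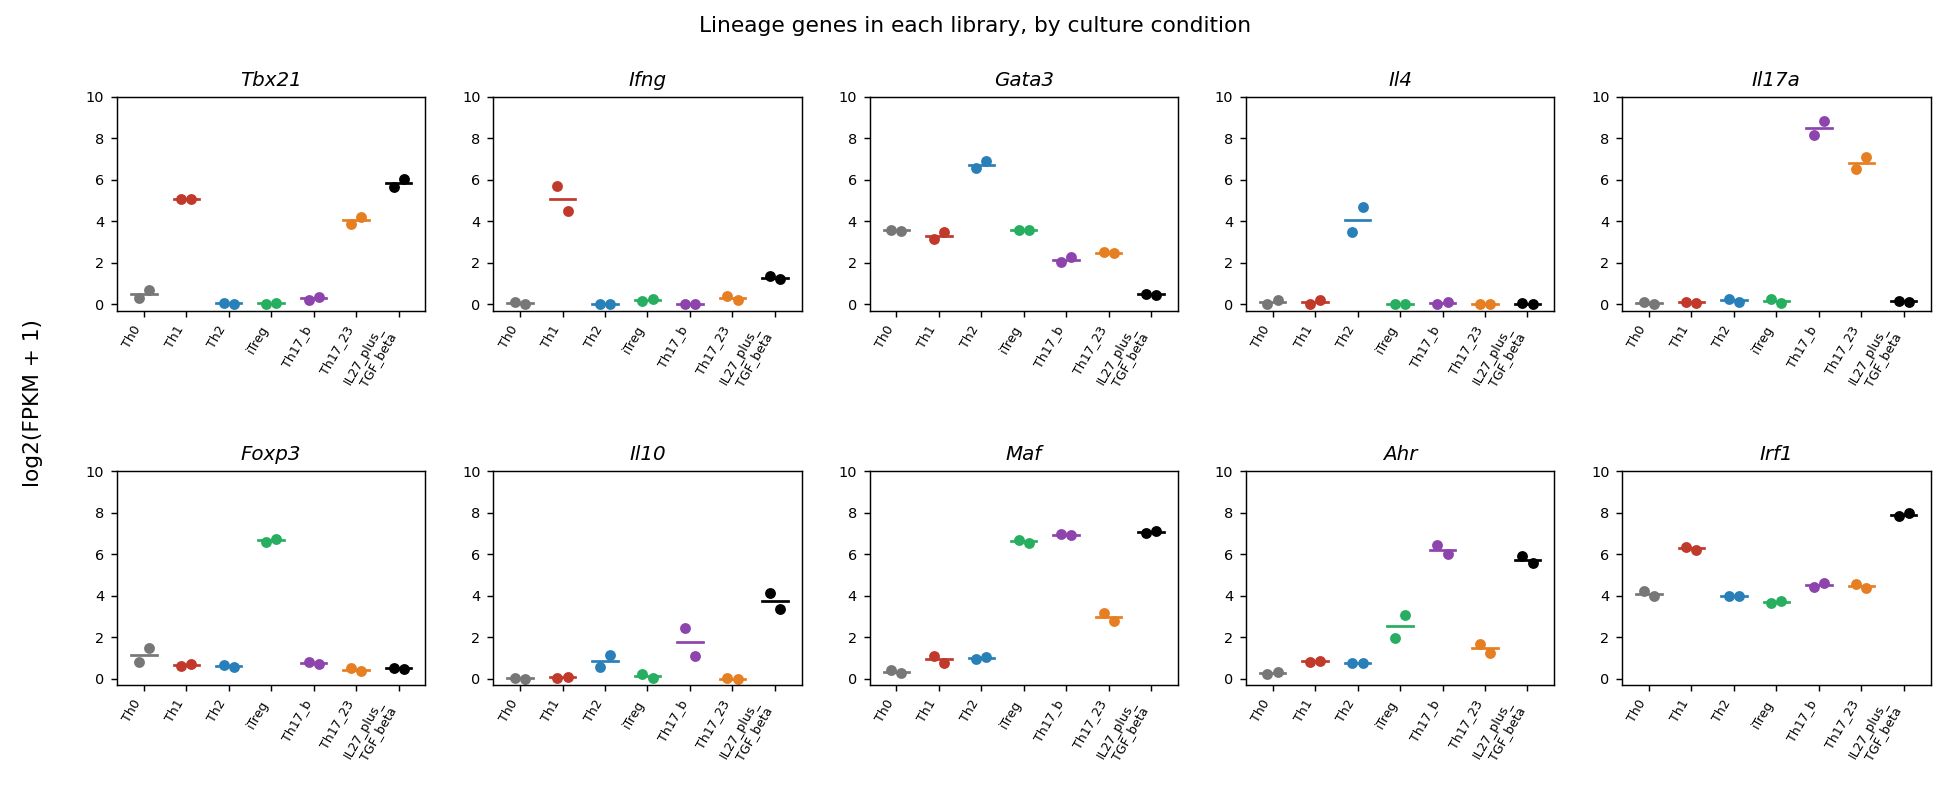
Levels of 10 lineage genes, as log2(FPKM + 1), in each of the 14 libraries, with 2 points per medium and a line at their mean. Foxp3 is high in the iTreg libraries, Il17a in the Th17_b and Th17_23 libraries, and Il10 and Irf1 are highest in the IL27_plus_TGF_beta libraries.

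**Figure D2:**
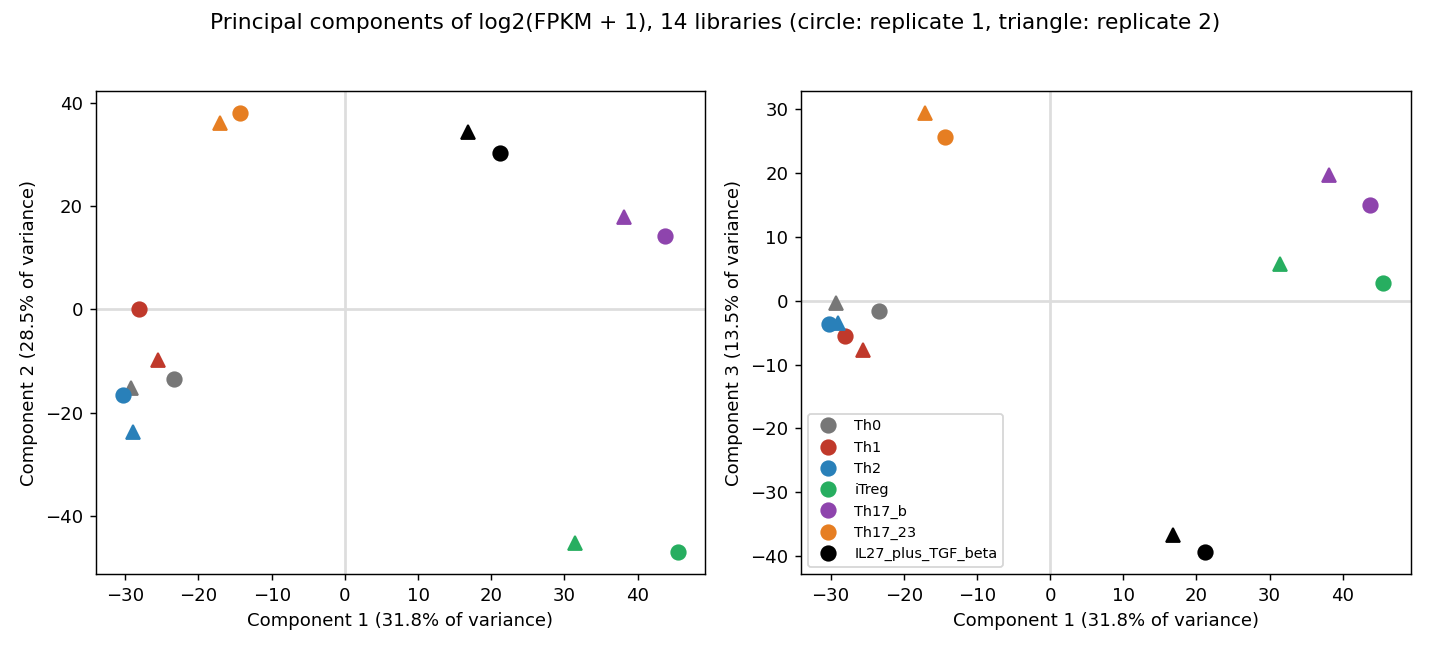
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library, coloured by medium and shaped by replicate. Component 3, with 13.5% of the variance, sets the IL27_plus_TGF_beta libraries apart from the others. The Th0, Th1 and Th2 libraries lie close together on components 1 and 3 and spread from -23.8 to 0.149 on component 2.

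In IL-27 and TGF-β, genes for T-bet, c-Maf, the aryl hydrocarbon receptor and IL-10 rose together. Compared with Th0, Tbx21 rose from 0.423 ± 0.255 to 57.8 ± 11.1 FPKM (log2 change 5.37 ± 0.12), Maf from 0.278 ± 0.0845 to 133 ± 4.43 (6.72 ± 0.11) and Ahr, a ligand-activated transcription factor, from 0.219 ± 0.0688 to 52.5 ± 9.02 (5.45 ± 0.30). Il10, the anti-inflammatory cytokine, rose from 0.0216 ± 0.0306 to 12.9 ± 5.13 FPKM (3.71 ± 0.36, adjusted p = 2.6e-05) and Il21 from 0.0468 ± 0.0194 to 36.7 ± 4.46 (5.17 ± 0.29). Ifng rose only to 1.46 ± 0.197 FPKM (1.25 ± 0.26) in a medium that holds an antibody to its protein. Gata3 fell from 10.9 ± 0.391 to 0.407 ± 0.0364 FPKM (-3.07 ± 0.12). Foxp3 stood at 0.421 ± 0.0486 against 1.28 ± 0.768 (-0.64 ± 0.18, adjusted p = 0.014); the change was -1.01 without Th0 replicate 1 and missed the threshold without Th0 replicate 2 (-0.27, adjusted p = 0.085) or IL27_plus_TGF_beta replicate 2 (-0.56, adjusted p = 0.097), in a fit of these groups alone (adjusted p = 0.076) and with the highest transcript of each gene in place of the sum (adjusted p = 0.23). The largest rises were in Ly6a, the surface antigen Sca-1, at 1150.1 ± 87.3 FPKM against 2.95 ± 0.213, the interferon-induced GTPase Iigp1 (7.22 ± 0.09), the chemokine Xcl1 (7.11 ± 0.35), Tox2 (6.58 ± 0.17), the gut homing receptor Gpr15 (6.02 ± 0.18), the cathepsin Ctsw (5.72 ± 0.15) and Ly6c1 (5.43 ± 0.35). Reads of the Ly6 genes can be shared between near-identical copies, so their levels are uncertain. The largest falls were in Nrn1 (-5.17 ± 0.22), Rcsd1 (-5.01 ± 0.09), Socs2 (-4.84 ± 0.44), Igfbp7 (-4.81 ± 0.18), Cish (-4.63 ± 0.39), Akr1c18 (-4.02 ± 0.26), Pdzk1ip1 (-4.02 ± 0.19), the CD30 ligand Tnfsf8 (-3.96 ± 0.20), Itih5 (-3.78 ± 0.14) and the activating receptor Cd226 (-3.72 ± 0.10).

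By gene group, the Th17 list rose although IL-17A itself did not: 16 of 20 members were higher and 0 lower, among them Cd5l (4.07 ± 0.16) and Ccr6 (3.35 ± 0.31), while Il17a was at 0.109 ± 0.0271 FPKM against 0.0370 ± 0.0523 (0.10 ± 0.21, adjusted p = 0.73; -0.02 without Th0 replicate 2). All 6 measured members of the non-pathogenic Th17 list rose, including Ikzf3 (3.88 ± 0.16) and the interleukin-1 antagonist Il1rn (1.98 ± 0.12). In camera, these lists passed with the preset correlation (adjusted p = 3.9e-09 and 1e-05) and with an estimated correlation (adjusted p = 0.036 for both). In the pathogenic Th17 list 5 members rose and 6 fell of 15, with Ccl3 higher (2.45 ± 0.31) and Casp1 lower (-1.38 ± 0.15).

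Interferon-induced genes rose in 32 of 48 and fell in 11. Irf1 went from 16.3 ± 1.94 to 239 ± 15.3 FPKM and Irgm1 from 6.96 ± 1.42 to 172 ± 11.2, and Gbp6 rose by 4.89 ± 0.09. Reads of the Gbp genes can also be shared between copies. The camera adjusted p was 3.9e-09, and 0.11 as an adjusted p with an estimated correlation. STAT3 targets rose in 13 of 17, with Stat3 (2.07 ± 0.09) and Rora (2.78 ± 0.16) among them (adjusted p = 5.9e-07, and adjusted p = 0.12 with an estimated correlation). Th1 genes rose in 9 and fell in 4 of 16, with Nkg7 (4.36 ± 0.20) and Twist1 (3.99 ± 0.21) higher and the granzyme Gzmb lower (-2.55 ± 0.43; adjusted p = 0.019, and adjusted p = 0.53 with an estimated correlation). Genes of type 1 regulatory cells, the IL-10 producers that IL-27 is known to induce, rose in 11 and fell in 4 of 17, with Lag3 at 252 ± 2.96 FPKM against 49.6 ± 1.07 (adjusted p = 0.001, and adjusted p = 0.15 with an estimated correlation). Coinhibitory receptors rose in 6 and fell in 3 of 13, with Tigit (3.75 ± 0.22), Pdcd1 (2.04 ± 0.08) and Pdpn (4.78 ± 0.14) higher (adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation). Regulatory T cell genes rose in 4 and fell in 9 of 18 (adjusted p = 0.51). In that list the ectonucleotidase Nt5e (4.46 ± 0.16) and Ikzf2 (2.05 ± 0.22) rose and Nrp1 fell (-2.53 ± 0.24).

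Follicular helper genes rose in 9 of 12, with Bcl6, their transcription factor, at 48.5 ± 0.782 FPKM against 1.95 ± 1.16 (adjusted p = 0.0011, and adjusted p = 0.29 with an estimated correlation). Chemokine genes rose in 5 of 6 (adjusted p = 0.0011, and adjusted p = 0.26 with an estimated correlation), with Cxcl10 at 13.9 ± 1.56 and Ccl20 at 12.5 ± 1.63 FPKM, both listed at 0 in Th0. Cytotoxic genes rose in 11 and fell in 4 of 16, with Gzmk at 8.20 ± 1.29 FPKM and listed at 0 in Th0 (adjusted p = 0.0042, and adjusted p = 0.29 with an estimated correlation). TGF-β target genes rose in 12 and fell in 4 of 21, with the feedback inhibitors Smad7 (1.16 ± 0.10) and Pmepa1 (3.10 ± 0.24) higher (adjusted p = 0.0018, and adjusted p = 0.29 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 22 and rose in 1, with Mvd (-1.54 ± 0.17) and Fdps (-1.34 ± 0.20) lower (adjusted p = 0.0035, and adjusted p = 0.73 with an estimated correlation). Genes of the unfolded protein response fell in 9 and rose in 2 of 19, with Trib3 (-3.13 ± 0.10) and the asparagine synthetase Asns (-3.51 ± 0.18) lower (adjusted p = 0.02, and adjusted p = 0.53 with an estimated correlation).

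IL-2 and STAT5 targets fell in 10 and rose in 4 of 18 (adjusted p = 0.09). The Th0 replicates differ in this list: Il2ra stood at 126 and 343 FPKM, Cish at 60.5 and 172, and Socs2 at 22.3 and 61.4. The change of Socs2 was -5.24 without Th0 replicate 1 and -4.45 without Th0 replicate 2, and that of Cish -4.97 and -4.30. With Th0 replicate 1 left out, 11 targets were lower, and with Th0 replicate 2 left out 8. Quiescence and lymphoid homing genes fell in 9 and rose in 4 of 15 (adjusted p = 0.095), with Il7r at 0.237 ± 0.0696 FPKM against 14.6 ± 4.54. No other list passed in camera. T cell activation genes rose in 6 and fell in 5 of 20 (adjusted p = 0.76), Th2 genes in 1 and 4 of 13 (0.56), cytokine genes in 6 and 8 of 26 (0.9), and chemokine receptor genes in 4 and 3 of 11 (0.43). Camera pointed up for the activation list, whose median was -0.13, and down for the cytokine list, with a median of -0.05 and a mean of 0.09. Cell cycle genes rose in 3 and fell in 10 of 40 (0.35), glycolysis genes in 9 and 4 of 19 (0.27), immediate early and heat shock genes in 3 and 3 of 12 (0.72), and p53 and apoptosis genes in 4 and 1 of 13 (0.23). Of the markers of other cells, 1 of 3 B cell and 1 of 3 dendritic cell markers fell and 1 of 3 myeloid markers rose. They were Cd79b (-0.81 ± 0.12), Batf3 (-1.88 ± 0.56) and Ctss (0.58 ± 0.10). The same 3 members of each of these lists were tested in every comparison, and the others were under the filter or not matched. Batf3 changed by -3.08 without Th0 replicate 1 and missed the threshold without Th0 replicate 2 (-0.67, adjusted p = 0.0915). It also missed it without IL27_plus_TGF_beta replicate 1 (-2.10, adjusted p = 0.0523) or 2 (-1.65, adjusted p = 0.116), with no replicate block (adjusted p = 0.0504) and in a fit of these groups alone (adjusted p = 0.0814). The 1 CD8 T cell marker tested, Cd8b1, was at 2.39 ± 0.0493 FPKM against 7.19 ± 0.759. No mitochondrial transcript was matched, and no natural killer, erythroid, or gamma-delta and NKT marker passed the filter.

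In all, limma called 5857 of 11511 genes, 2530 higher and 3327 lower in IL-27 and TGF-β, of which 1126 changed by a log2 of 1 or more (1712 with a pseudocount of 0.1, which shrinks the change of low genes less). Those higher and lower numbered 2875 and 3175 with quantile normalization and 2936 and 3114 with median scaling. None of the called genes moved in opposite directions in replicates 1 and 2, which the calling itself favours, since it rests on these changes. Of the 1126 genes, 960 changed by a log2 of 1 or more in the same direction in both replicates. Across all tested genes, the changes in the replicates correlated at 0.906. Adjusted over the list alone, the counts moved by 1 gene in 5 lists: interferon targets higher (33), quiescence (10), cell cycle (9), cholesterol (14) and unfolded protein response genes lower (10).

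**Figure D3:**
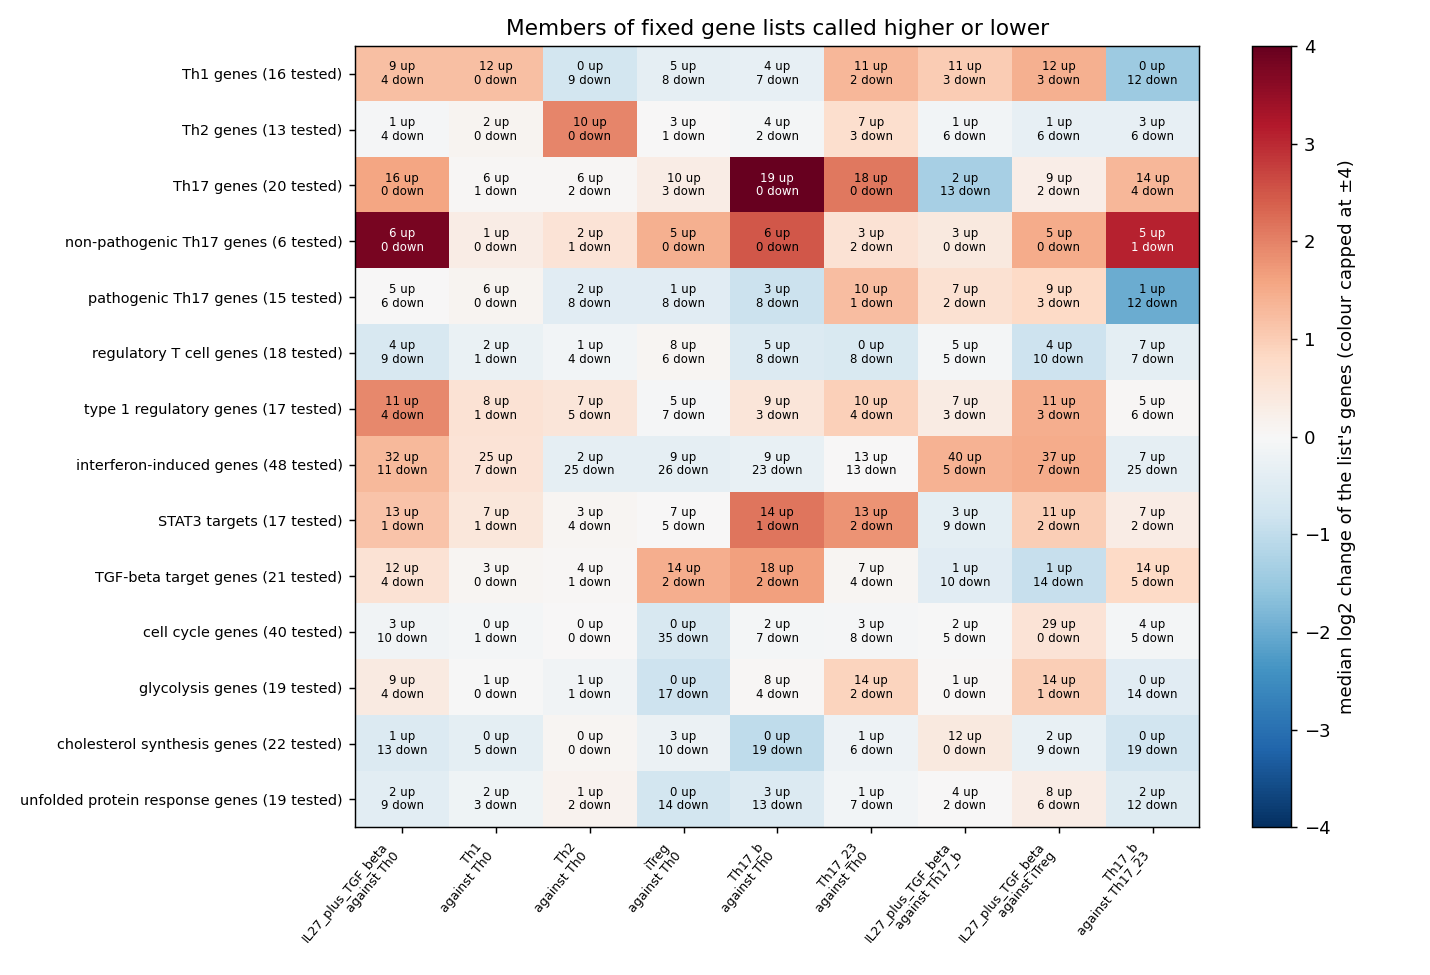
Counts of members called higher or lower for 14 gene lists in the 9 comparisons, over a colour that gives the list's median log2 change, capped at 4. The Th17 list has 19 members higher in Th17_b, 18 in Th17_23 and 16 in IL27_plus_TGF_beta, each against Th0.

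Th1 cells, which received IL-12 and, like Th0, an antibody to IL-4, raised type 1 genes. Their medium holds no antibody to IFN-γ per the labels, while that of Th0 does. Against Th0, Ifng went from 0.0356 ± 0.0504 to 36.1 ± 20.5 FPKM (5.04 ± 0.26), Tbx21 rose by 4.56 ± 0.12, and Gzmb went from 9.83 ± 4.01 to 115 ± 19.4. Ly6a (6.94 ± 0.24), Plac8 (5.02 ± 0.41) and Ctla2a (4.03 ± 0.37) rose most besides, and Atp6v0c-ps2 (-3.33 ± 0.29), Igfbp7 (-1.85 ± 0.18), Nrgn (-1.78 ± 0.33), the homing regulator Klf2 (-1.57 ± 0.21) and Pdzk1ip1 (-1.52 ± 0.19) fell most. The Th1 list had 12 of 16 members higher and 0 lower (adjusted p = 1.9e-17, and adjusted p = 0.068 with an estimated correlation). Interferon-induced genes were higher in 25 and lower in 7 of 48 (adjusted p = 6.2e-17, and adjusted p = 0.068 with an estimated correlation). Type 1 regulatory genes were higher in 8 of 17 (adjusted p = 3.2e-06, and adjusted p = 0.068 with an estimated correlation), but Il10 was not called, at 0.0487 ± 0.0113 FPKM. Cytotoxic genes rose in 7 of 16 (adjusted p = 2.9e-05, and adjusted p = 0.18 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 22 (adjusted p = 4.1e-05, and adjusted p = 0.52 with an estimated correlation). IL-2 and STAT5 targets rose in 6 of 18 (camera adjusted p = 0.00012, and adjusted p = 0.52 with an estimated correlation), a list in which the Th0 replicates differ. Per the labels, an antibody to IL-2 is named, without a dose, for the Th0 medium and not for that of Th1. How far it neutralized IL-2 in Th0 was not tested. No marker of another cell type was called, and p53 and apoptosis genes rose in 3 and fell in 2 of 13 (adjusted p = 0.025, and adjusted p = 0.52 with an estimated correlation; 1 higher without Th1 replicate 1, 1 and 1 without Th0 replicates 1 and 2). Immediate early and heat shock genes rose in 2 and fell in 2 of 12 (adjusted p = 0.37). With calls over the list alone 5 p53 and apoptosis and 3 immediate early and heat shock genes rose, and 1 B cell and 1 CD8 T cell marker were lower. The counts of the other lists adjusted over the list alone were 14, 29, 9, 9 and 7 higher for the Th1, interferon, type 1 regulatory, cytotoxic and IL-2 lists, and 9, 2 and 8 lower for the interferon, cytotoxic and cholesterol lists. Without Th1 replicate 1 the counts were 4 cytotoxic, 5 type 1 regulatory and 3 IL-2 genes higher, and without Th0 replicate 1 5 type 1 regulatory and 3 IL-2 genes. The lower cholesterol genes numbered 2, 1, 1 and 2 without Th1 replicate 1, Th1 replicate 2, Th0 replicate 1 and Th0 replicate 2, and Nrgn missed the threshold without Th1 replicate 1 (-1.43, adjusted p = 0.08) and without Th0 replicate 1 (-1.63, adjusted p = 0.079). In a fit of Th1 and Th0 alone, Klf2, Nrgn and Pdzk1ip1 missed it too (adjusted p = 0.073, 0.072 and 0.079). Limma called 1611 genes, 737 higher and 874 lower, and 187 by a log2 of 1 or more (393 with a pseudocount of 0.1 and 121 in a fit of these groups alone). More were higher than lower with quantile normalization (901 and 793), median scaling (878 and 754), no filter (686 and 651), these groups alone (135 and 34), without Th1 replicate 1 (303 and 196) or 2 (563 and 352) and without Th0 replicate 1 (314 and 205) or 2 (471 and 368), so the balance was not settled. With no replicate block the count was 966, 471 and 495 higher and lower. The count rests on single libraries and on the other groups: it was 499 without Th1 replicate 1, 915 without Th1 replicate 2, 519 and 839 without Th0 replicates 1 and 2, and 169 in a fit of these groups alone.

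Th2 cells, grown with IL-4 and, like Th0, with an antibody to IFN-γ, raised Il4 from 0.0733 ± 0.104 to 17.4 ± 10.1 FPKM (3.98 ± 0.26) and Gata3 by 3.15 ± 0.12. The antibody to IL-2 of the Th0 medium is not named for Th2. The largest rises were in the motor protein gene Myo6, at 215 ± 49.9 FPKM against 0.934 ± 0.219, Csf1 (5.32 ± 0.28), Pros1 (4.73 ± 0.16), Tanc2 (4.42 ± 0.11) and Epas1 (4.14 ± 0.18), which encodes HIF-2α. The largest falls were in Igfbp7 (-4.44 ± 0.18), the IL-18 receptor Il18r1 (-3.58 ± 0.20), Pdzk1ip1 (-3.30 ± 0.19), Gbp5 (-3.04 ± 0.17) and Gpr65 (-3.02 ± 0.28). The Th2 list rose in 10 of 13, with Nfil3 (2.88 ± 0.13) and Asb2 (3.07 ± 0.17) among them (adjusted p = 7e-16, and adjusted p = 0.088 with an estimated correlation). Il13 was not called, at 0.912 ± 0.982 FPKM (0.76 ± 0.39, adjusted p = 0.22), but passed with a pseudocount of 0.1 (adjusted p = 0.026). Markers of other cells moved as well: the macrophage marker Adgre1 stood at 2.02 ± 0.659 FPKM and was listed at 0 in Th0, and Ctss, which encodes cathepsin S, fell (-0.91 ± 0.10). The dendritic cell markers H2-Ab1 (0.67 ± 0.16) and Batf3 (3.20 ± 0.56) were higher, 2 of 3 (adjusted p = 0.049, and adjusted p = 0.27 with an estimated correlation; adjusted p = 0.076 with no replicate block), but only 1 without Th2 replicate 1 or without Th0 replicate 2. H2-Ab1 missed the threshold in these fits (0.56, adjusted p = 0.099, and 0.46, adjusted p = 0.16), with a pseudocount of 0.1 (adjusted p = 0.054) and with no replicate block (adjusted p = 0.097). Batf3 changed by 2.00 without Th0 replicate 1 and missed it in a fit of these groups alone (adjusted p = 0.058). It stood at 6.38 ± 7.89 FPKM in Th0. The other dendritic cell markers of the list were under the filter in every medium or not matched. Immediate early and heat shock genes rose in 1 and fell in 2 of 12 (adjusted p = 0.88), and p53 and apoptosis genes rose in 1 and fell in 4 of 13 (adjusted p = 0.98), 2 higher over the list alone. Interferon-induced genes fell in 25 and rose in 2 of 48 (adjusted p = 1.5e-06, and adjusted p = 0.25 with an estimated correlation), and Th1 genes fell in 9 of 16 (adjusted p = 0.0016, and adjusted p = 0.55 with an estimated correlation). The Th1 genes that fell numbered 5 without Th2 replicate 2 and 5 without Th0 replicate 2. Counts adjusted over the list alone were 3 higher and 26 lower for interferon targets, 1 higher and 10 lower for Th1 genes, and as above for Th2 genes. Limma called 2058 genes, 647 higher and 1411 lower (31.4% higher). With quantile normalization 49.0% and with median scaling 47.0% of the calls were higher. Those higher and lower numbered 369 and 613 without Th2 replicate 2, 406 and 814 without Th0 replicate 1 and 400 and 678 without Th0 replicate 2. The count was 982 without Th2 replicate 2, 1220 and 1078 without Th0 replicates 1 and 2, and 936 in a fit of these groups alone.

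iTreg cells, grown with TGF-β and IL-2, turned on Foxp3 and lowered genes of the cell cycle and glycolysis. The antibody to IL-2 of the Th0 medium is not named for iTreg. Foxp3 went from 1.28 ± 0.768 to 100.3 ± 5.46 FPKM (5.51 ± 0.18). Ctsw (6.34 ± 0.15), Maf (6.26 ± 0.11), the ectonucleotidase Nt5e (5.78 ± 0.16) and Apol9b (5.64 ± 0.18) rose with it, and Nrn1 (-4.82 ± 0.22), Gbp5 (-3.51 ± 0.17), Gzmb (-3.34 ± 0.43), Gbp2 (-3.10 ± 0.13) and Casp4 (-2.99 ± 0.15) fell most. Cell cycle genes fell in 35 of 40 and rose in 0, with the replication factors Mcm3 at 45.6 ± 14.5 FPKM against 143 ± 12.2 and Mcm5 at 39.3 ± 6.56 against 97.2 ± 9.86 (adjusted p = 3.8e-06, and adjusted p = 0.72 with an estimated correlation). Glycolysis genes fell in 17 of 19, with the hexokinase Hk2 lower (-2.32 ± 0.20; adjusted p = 0.0012, and adjusted p = 0.72 with an estimated correlation). Unfolded protein response genes fell in 14 of 19, with the chaperone Hspa5 at 92.6 ± 9.60 FPKM against 223 ± 36.2 (adjusted p = 0.0078, and adjusted p = 0.69 with an estimated correlation). TGF-β targets rose in 14 and fell in 2 of 21, with Smad7 (2.91 ± 0.10), Ski (2.02 ± 0.09) and Ldlrad4 (4.55 ± 0.19) higher (adjusted p = 4e-07, and adjusted p = 0.14 with an estimated correlation). Chemokine receptors rose in 8 of 11, with Ccr8 at 194 ± 27.5 FPKM against 10.9 ± 1.62 and Ccr6 higher by 4.75 ± 0.31 (adjusted p = 0.00039, and adjusted p = 0.36 with an estimated correlation). Quiescence and homing genes rose in 10 of 15, with Foxo1 (1.24 ± 0.09) and S1pr1 (1.43 ± 0.14) among them (adjusted p = 0.0012, and adjusted p = 0.13 with an estimated correlation). The regulatory T cell list was split, with 8 higher and 6 lower of 18 (adjusted p = 0.13), Entpd1 higher (2.13 ± 0.17) and Tnfrsf18 lower (-1.90 ± 0.16). Of the 4 IL-2 and STAT5 targets with the smallest p, Ccr8 was higher and Tnfrsf18, Cdk6 (-2.08 ± 0.23) and Tnfrsf4 (-1.54 ± 0.18) lower. Replicates differed in that list, by a median log2 of -0.56 in iTreg and -0.81 in Th0 for replicate 1 minus replicate 2. Markers of other cells and stress genes moved too. Of the myeloid markers 2 of 3 were higher, with Ctss at 142 ± 8.75 FPKM against 65.0 ± 2.75 (adjusted p = 0.11; 1 without iTreg replicate 1 or Th0 replicate 1). The B cell marker Cd79a was higher (0.50 ± 0.11), while the dendritic cell markers H2-Ab1 (-2.02 ± 0.16) and Batf3 (-1.75 ± 0.56) and the CD8 T cell marker Cd8b1 (-0.46 ± 0.11) were lower. Batf3 changed by -2.95 without Th0 replicate 1 and missed the threshold without Th0 replicate 2 (-0.55, adjusted p = 0.137). It also missed it without iTreg replicate 1 (-1.75, adjusted p = 0.077) or 2 (-1.74, adjusted p = 0.0703), with no replicate block (adjusted p = 0.0536), with no filter (adjusted p = 0.0501) and in a fit of these groups alone (adjusted p = 0.0666). Immediate early and heat shock genes fell in 8 and rose in 1 of 12 (adjusted p = 0.18), with Hsp90aa1 (-1.41 ± 0.14) and Hsph1 (-0.88 ± 0.10) lower. p53 and apoptosis genes rose in 3 and fell in 7 of 13 (adjusted p = 0.43). When adjusted over the list alone, 18 glycolysis genes fell, and the counts of the other lists named here did not move. Limma called 7320 genes, 2610 higher and 4710 lower (35.7% higher). Quantile normalization raised the median change of all genes by 0.11, from -0.13, and made 46.7% of the calls higher. Under it 33 cell cycle and 16 glycolysis genes were lower.

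Th17_b cells, grown with TGF-β and IL-6, held the highest Il17a and Il17f. Il17f went from 0.237 ± 0.0813 to 835 ± 102 FPKM (9.40 ± 0.23) and Il17a rose by 8.44 ± 0.21. Maf (6.60 ± 0.11), Ly6a (6.14 ± 0.24) and Gpr15 (5.96 ± 0.18) followed, and Dapl1 (-4.90 ± 0.09), Socs2 (-4.80 ± 0.44), Nrn1 (-4.24 ± 0.22), Stc2 (-4.16 ± 0.24) and Asns (-4.12 ± 0.18) fell most. The Th17 list rose in 19 of 20, with Il1r1 (5.55 ± 0.08) and Il23r (3.88 ± 0.15) among them, and passed with an estimated correlation too (adjusted p = 6.7e-15, and adjusted p = 0.01). STAT3 targets rose in 14 of 17 (adjusted p = 2.9e-07, and adjusted p = 0.13 with an estimated correlation), TGF-β targets in 18 of 21 with Smad7 higher by 1.98 ± 0.10 (adjusted p = 1e-06, and adjusted p = 0.18 with an estimated correlation), all 6 non-pathogenic Th17 genes (adjusted p = 0.00024, and adjusted p = 0.08 with an estimated correlation), and 8 of 11 chemokine receptors with Cxcr6 at 32.7 ± 0.551 FPKM against 0.912 ± 0.562 (adjusted p = 0.00091, and adjusted p = 0.48 with an estimated correlation). Cholesterol synthesis genes fell in 19 of 22, with Dhcr7 (-1.54 ± 0.12) and Stard4 (-1.37 ± 0.13) lower (adjusted p = 1.5e-06, and adjusted p = 0.67 with an estimated correlation). IL-2 and STAT5 targets, which differ between the Th0 replicates, fell in 11 and rose in 2 of 18 (adjusted p = 0.023, and adjusted p = 0.71 with an estimated correlation), but did not pass with no replicate block (adjusted p = 0.058); both media hold an antibody to IL-2. Of the markers of other cells Cd8b1 (-0.45 ± 0.11), the B cell marker Cd79b (-0.83 ± 0.12) and the dendritic cell markers Batf3 (-2.01 ± 0.56) and H2-Eb1 (-0.47 ± 0.14) were lower. Immediate early and heat shock genes rose in 4 and fell in 4 of 12 (adjusted p = 0.88), and p53 and apoptosis genes rose in 2 and fell in 8 of 13 (adjusted p = 0.15). Cd8b1 missed the threshold without Th17_b replicate 1 (-0.38, adjusted p = 0.059). H2-Eb1 did so without Th17_b replicate 1 (-0.49, adjusted p = 0.0684) or 2 (-0.46, adjusted p = 0.0838) and without Th0 replicate 2 (-0.41, adjusted p = 0.113). Batf3 did so without Th17_b replicate 2 (-1.44, adjusted p = 0.116) and in a fit of these groups alone (adjusted p = 0.122), and changed by -3.21 and -0.81 without Th0 replicates 1 and 2. Adjusted over the list alone, 3 IL-2 targets rose, and the counts of the other lists named here did not move. Limma called 6275 genes, 2917 higher and 3358 lower, 1207 of them by a log2 of 1 or more; without Th17_b replicate 1, 2460 and 2442 were higher and lower.

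Th17_23 cells, grown with IL-1β, IL-6, IL-23 and antibodies to TGF-β, raised IL-17 genes and type 1 genes. Il17f reached 425 ± 88.3 FPKM (8.41 ± 0.23) and Il17a rose by 6.77 ± 0.21, while Tbx21 went from 0.423 ± 0.255 to 15.7 ± 2.65 FPKM. Ly6a (7.23 ± 0.24), the protease inhibitor Timp1 (7.19 ± 0.33) and S100a6 (7.04 ± 0.39) rose as well, and Igfbp7 (-3.36 ± 0.18), Socs2 (-3.32 ± 0.44), Akr1c12 (-3.00 ± 0.22), Chchd10 (-2.80 ± 0.13) and the latent TGF-β anchor Lrrc32 (-2.74 ± 0.45) fell most. The Th17 list rose in 18 of 20 and passed with an estimated correlation (adjusted p = 5.8e-11, and adjusted p = 0.024). Il22 stood at 102 ± 26.0 FPKM and was listed at 0 in Th0, and its reads can be shared with the near copy Iltifb. Pathogenic Th17 genes rose in 10 of 15, with Il33 (4.41 ± 0.15) and Il23r (3.58 ± 0.15) among them (adjusted p = 0.0016, and adjusted p = 0.48 with an estimated correlation). Th1 genes rose in 11 of 16 (adjusted p = 0.0016, and adjusted p = 0.48 with an estimated correlation), but Ifng was not called, at 0.257 ± 0.121 FPKM (adjusted p = 0.39). It passed with a pseudocount of 0.1 (adjusted p = 0.0087) and in a fit of these groups alone (adjusted p = 0.04). Glycolysis genes rose in 14 of 19, with Ldha at 1712 ± 3.16 FPKM against 809 ± 61.6 and Slc2a1, the glucose transporter GLUT1, higher by 1.24 ± 0.16 (adjusted p = 0.0016, and adjusted p = 0.63 with an estimated correlation). Cytotoxic genes rose in 10 of 16, with Crtam (3.78 ± 0.27) and the perforin gene Prf1 (1.90 ± 0.13) higher (adjusted p = 0.0056, and adjusted p = 0.48 with an estimated correlation). Regulatory T cell genes fell in 8 of 18 and rose in 0, with Izumo1r (-1.60 ± 0.22) and Nt5e (-1.16 ± 0.16) lower (adjusted p = 0.0072, and adjusted p = 0.59 with an estimated correlation). Pathogenic genes higher numbered 6 without Th0 replicate 1, and Th1 genes higher 7 without Th0 replicate 1 and 7 without Th17_23 replicate 2. The myeloid marker Ctss (-1.21 ± 0.10), the B cell marker Cd79b (-0.68 ± 0.12) and the CD8 T cell marker Cd8b1 (-0.36 ± 0.11) were lower, and the dendritic cell marker H2-Ab1 (0.87 ± 0.16) and the B cell marker Ebf1 (2.25 ± 0.16) higher. Cd8b1 missed the threshold without Th17_23 replicate 1 (-0.20, adjusted p = 0.202), Th0 replicate 1 (-0.38, adjusted p = 0.0767) or Th0 replicate 2 (-0.34, adjusted p = 0.104), and with no replicate block (adjusted p = 0.0648). Immediate early and heat shock genes rose in 4, with Hsp90aa1 (0.96 ± 0.14) and Hsph1 (1.25 ± 0.10) among them, and fell in 2 of 12 (adjusted p = 0.55; 3 lower over the list alone). p53 and apoptosis genes rose in 9 and fell in 2 of 13 (adjusted p = 0.076). As adjusted over the list alone, 19 Th17 genes rose, and the counts of the other lists named before these did not move. Limma called 5684 genes, 3043 higher and 2641 lower, 774 of them by a log2 of 1 or more (1271 with a pseudocount of 0.1). With quantile normalization 2692 and 3144 were higher and lower, so that the majority turned, and with median scaling 2959 and 2911. The higher genes numbered 2028 without Th0 replicate 1.

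Set against Th17_b, whose medium holds the same TGF-β with IL-6 in place of IL-27 and has no antibody to IL-4, the IL-27 and TGF-β cells held less of the IL-17 genes and more of the interferon-induced and type 1 genes. Il17a stood at 0.109 ± 0.0271 FPKM against 367 ± 115 (-8.34 ± 0.21), Il17f was lower (-7.34 ± 0.23), and Il1r1 (-5.49 ± 0.08), Il7r (-5.17 ± 0.19) and Serpinb1a (-5.15 ± 0.23) were lower. Iigp1 (7.58 ± 0.09), Nkg7 (6.80 ± 0.20), Tbx21 (5.56 ± 0.12), Xcl1 (5.45 ± 0.35) and Gbp6 (5.09 ± 0.09) were higher. Il10 stood at 12.9 ± 5.13 against 2.78 ± 2.34 FPKM (1.98 ± 0.36, adjusted p = 0.0019). Maf, at 133 ± 4.43 against 123 ± 5.68, Ahr, at 52.5 ± 9.02 against 74.3 ± 15.3, and Il21, at 36.7 ± 4.46 against 58.8 ± 17.4, were not called different (adjusted p = 0.43, 0.24 and 0.12). Ahr and Il21 passed in a fit of these groups alone (adjusted p = 0.0021 and 0.0091), and Il21 without Th17_b replicate 1 (-1.03, adjusted p = 0.0499). Interferon-induced genes were higher in 40 and lower in 5 of 48 (adjusted p = 2.8e-19, and adjusted p = 0.052 with an estimated correlation), and Th17 genes lower in 13 and higher in 2 of 20 (adjusted p = 3e-05, and adjusted p = 0.084 with an estimated correlation). Th1 genes were higher in 11 of 16 (adjusted p = 0.00039, and adjusted p = 0.33 with an estimated correlation). Coinhibitory receptors were higher in 9 of 13, with Tigit at 173 ± 10.9 FPKM against 15.3 ± 0.817 and Ctla4 lower at 80.4 ± 1.90 against 236 ± 42.1 (adjusted p = 0.0027, and adjusted p = 0.27 with an estimated correlation). Cytotoxic genes were higher in 9 of 16 (adjusted p = 0.00032, and adjusted p = 0.27 with an estimated correlation) and chemokine genes in 5 of 6 (adjusted p = 0.0016, and adjusted p = 0.27 with an estimated correlation). TGF-β targets were lower in 10 of 21, with Smad3 (-2.93 ± 0.14) and Smad7 (-0.82 ± 0.10) among them (adjusted p = 0.0017, and adjusted p = 0.33 with an estimated correlation). Chemokine receptors were lower in 7 of 11, with Cxcr6 at 0.460 ± 0.216 FPKM (adjusted p = 0.0089, and adjusted p = 0.38 with an estimated correlation), quiescence and homing genes lower in 9 of 15 (adjusted p = 0.0069, and adjusted p = 0.19 with an estimated correlation), and cholesterol synthesis genes higher in 12 of 22, with Cyp51 at 77.3 ± 4.83 FPKM against 43.3 ± 0.311 (adjusted p = 0.00031, and adjusted p = 0.5 with an estimated correlation). The cholesterol genes higher numbered 7 without either Th17_b replicate and 6 without either IL27_plus_TGF_beta replicate. In a fit of these groups alone 16 TGF-β targets were lower. The CD8 T cell marker Cd8b1 was lower (-0.82 ± 0.11) and the myeloid marker Ctss higher (0.83 ± 0.10). Immediate early and heat shock genes were higher in 2 and lower in 0 of 12 (adjusted p = 0.44). p53 and apoptosis genes were higher in 8 and lower in 1 of 13 (adjusted p = 0.0035, and adjusted p = 0.33 with an estimated correlation; 5 higher without Th17_b replicate 1). With calls adjusted over the list alone, 10 cytotoxic genes were higher and 1 lower, and the counts of the other lists named here did not move. Limma called 4442 genes, 1917 higher and 2525 lower (43.2% higher). With median scaling 55.5% and with quantile normalization 49.1% of the calls were higher. The higher genes numbered 1237 and 1196 without IL27_plus_TGF_beta replicates 1 and 2 and 1214 without Th17_b replicate 1.

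Against iTreg cells, whose medium holds more TGF-β with IL-2, the IL-27 and TGF-β cells had almost no Foxp3 (0.421 ± 0.0486 against 100.3 ± 5.46 FPKM, -6.15 ± 0.18) and more Il10 (12.9 ± 5.13 against 0.0953 ± 0.0939, 3.62 ± 0.36). The IL-27 and TGF-β medium holds an antibody to IL-2, so IL-27, the dose of TGF-β and IL-2 cannot be told apart here. Ly6a (9.00 ± 0.24), Iigp1 (7.77 ± 0.09), Gbp2 (6.56 ± 0.13), Gbp6 (6.23 ± 0.09) and Tox2 (6.13 ± 0.17) were higher, and Nupr1 (-5.21 ± 0.33), Socs2 (-4.90 ± 0.44) and Rcsd1 (-4.83 ± 0.09) lower. Maf stood at 133 ± 4.43 against 97.3 ± 5.74 FPKM (0.45 ± 0.11, adjusted p = 0.0055), a difference that missed the threshold without IL27_plus_TGF_beta replicate 2 (0.34, adjusted p = 0.066) and with quantile normalization (0.23, adjusted p = 0.098). Interferon-induced genes were higher in 37 of 48 (adjusted p = 4.6e-07, and adjusted p = 0.26 with an estimated correlation). Cell cycle genes were higher in 29 of 40, with Mcm5 at 105 ± 1.90 FPKM against 39.3 ± 6.56 (adjusted p = 0.00062, and adjusted p = 0.58 with an estimated correlation), and glycolysis genes in 14 of 19, with Hk2 (2.64 ± 0.20) and Pgam1 (1.74 ± 0.17) among them (adjusted p = 0.003, and adjusted p = 0.54 with an estimated correlation). TGF-β targets were lower in 14 of 21, with Smad7 (-1.75 ± 0.10) and Tgfbr1 (-2.13 ± 0.20) among them (adjusted p = 0.00062, and adjusted p = 0.48 with an estimated correlation). Regulatory T cell genes were lower in 10 and higher in 4 of 18 (adjusted p = 0.028, and adjusted p = 0.53 with an estimated correlation), and quiescence and homing genes lower in 10 of 15 (adjusted p = 0.0035, and adjusted p = 0.26 with an estimated correlation). Of the other markers Cd8b1 (-0.82 ± 0.11), Ctss (-0.53 ± 0.10), Itgam (-1.27 ± 0.22), Cd79a (-0.56 ± 0.11) and Cd79b (-0.62 ± 0.12) were lower and H2-Ab1 higher (1.71 ± 0.16), and immediate early and heat shock genes were higher in 7 and lower in 2 of 12, with Hsp90aa1 among them (1.69 ± 0.14; adjusted p = 0.15), and 8 higher over the list alone. p53 and apoptosis genes were higher in 8 and lower in 3 of 13 (adjusted p = 0.27). In calls adjusted over the list alone, 1 cell cycle gene was lower, and 15 glycolysis and 3 quiescence genes higher. Limma called 7643 genes, 4427 higher and 3216 lower (57.9% higher, and 50.8% with quantile normalization and 51.7% with median scaling), and 1 called gene moved in opposite directions in the 2 replicates.

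The forms of Th17 culture differed from each other. Th17_b held more Il17a (367 ± 115 against 114 ± 32.7 FPKM, 1.67 ± 0.21), Maf (3.97 ± 0.11), Nt5e (6.22 ± 0.16), the water channel Aqp3 (6.11 ± 0.25), Gpr15 (5.92 ± 0.18), Ccl20 (4.94 ± 0.33) and Ahr (4.75 ± 0.30). Th17_23 held more Il22 (102 ± 26.0 against 0.0807 ± 0.0381), Nkg7 (-5.89 ± 0.20), Lum (-5.12 ± 0.18), Gzmb (-4.93 ± 0.43), Pdzk1ip1 (-4.75 ± 0.19) and Tbx21 (-3.75 ± 0.12). Il23r was not called different, at 14.1 ± 2.80 against 11.1 ± 1.05 FPKM (adjusted p = 0.1), except without Th17_b replicate 1 (0.49, adjusted p = 0.045). Pathogenic Th17 genes were lower in Th17_b in 12 of 15 (adjusted p = 0.00075, and adjusted p = 0.33 with an estimated correlation), non-pathogenic Th17 genes higher in 5 of 6 (adjusted p = 0.0029, and adjusted p = 0.21 with an estimated correlation), and Th17 genes higher in 14 and lower in 4 of 20 (adjusted p = 7.2e-05, and adjusted p = 0.17 with an estimated correlation). Th1 genes were lower in 12 of 16 (adjusted p = 0.00028, and adjusted p = 0.33 with an estimated correlation), T cell activation genes in 14 of 20, with Il2 at 1.12 ± 0.851 FPKM against 52.6 ± 5.05 (adjusted p = 0.00056, and adjusted p = 0.33 with an estimated correlation), and glycolysis genes in 14 of 19 (adjusted p = 0.0021, and adjusted p = 0.56 with an estimated correlation). Cholesterol synthesis genes were lower in 19 of 22 (adjusted p = 9.4e-05, and adjusted p = 0.52 with an estimated correlation), and p53 and apoptosis genes in 11 of 13, with Fas lower (-1.34 ± 0.14; adjusted p = 0.0027, and adjusted p = 0.33 with an estimated correlation). TGF-β targets were higher in 14 and lower in 5 of 21, with Smad7 higher (1.77 ± 0.10; adjusted p = 0.00075, and adjusted p = 0.33 with an estimated correlation). The glycolysis genes lower numbered 9, 8, 8 and 9 without Th17_b replicates 1 and 2 and Th17_23 replicates 1 and 2. All 3 dendritic cell markers were lower, H2-Ab1 (-1.08 ± 0.16), H2-Eb1 (-0.51 ± 0.14) and Batf3 (-2.88 ± 0.56) (adjusted p = 0.095; 2 without either Th17_b replicate or without Th17_23 replicate 2). H2-Eb1 was the marker that missed the threshold there (-0.52, adjusted p = 0.0565, -0.49, adjusted p = 0.0637, and -0.38, adjusted p = 0.113). Ebf1 was lower (-2.23 ± 0.16) and Ctss higher (0.96 ± 0.10), and immediate early and heat shock genes were higher in 1 and lower in 5 of 12 (adjusted p = 0.33), with Hsp90aa1 lower (-1.03 ± 0.14). By calls adjusted over the list alone, 2 pathogenic Th17 genes were higher, 15 activation, 20 cholesterol and 6 TGF-β genes lower, and 1 activation gene higher. Limma called 6423 genes, 2700 higher and 3723 lower in Th17_b (42.0% higher, and 49.6% with quantile normalization and 42.9% with median scaling).

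Genes that were higher in 1 medium than in each of the other 6, by a log2 of 1 or more and called in all 6 tests, numbered 127 in IL-27 and TGF-β, 132 in iTreg, 114 in Th17_23, 78 in Th17_b, 72 in Th2, 18 in Th1 and 2 in Th0, where they were Nrn1 and Kcnj8. The Th1 count was 11 without Th1 replicate 1 and 27 without Th1 replicate 2. The Th0 count was 5 and 10 without Th0 replicates 1 and 2 and 1 without Th1 replicate 1, and 1 with no replicate block. In IL-27 and TGF-β, 23 of the genes had no symbol of their own or were small RNAs. The largest margins among the rest were in Ch25h, an enzyme that makes 25-hydroxycholesterol, at 20.6 FPKM against 0.0230 in the next medium, the chemokine Cxcl10 at 13.9 against 0.149, Iigp1 at 288 against 21.8 in Th1, Tmem158 at 65.4 against 4.73, and Xcl1 at 206 against 23.4 in iTreg. Gfra4, Tgtp1, Mpzl2, Cxcl17 and Gzmk came next, and reads of Tgtp1 can be shared with its near copy Tgtp2. Il10, Irf1 and Tigit also met these criteria.

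The change under IL-27 and TGF-β from Th0 was set beside that of each subset. Across 11511 genes, which are not independent replicates, Pearson's r was 0.634 with Th17_b, 0.485 with Th17_23, 0.372 with Th1, 0.312 with iTreg and 0.132 with Th2, and Spearman's rho 0.655, 0.511, 0.234, 0.247 and 0.143. The Th0 libraries are shared, and unchanged groups set against them gave r = 0.505 in 100 simulations. For groups of equal size that hold noise alone, sharing a baseline fixes r near this value. It is therefore no bar for the values of r above, and covariances are compared instead. The covariances were 0.356, 0.225, 0.102, 0.166 and 0.0411 in that order, beside a simulated covariance of 0.0130. In Th17_b, 1576 genes were called higher in both and 2249 lower in both, where independent lists would share 641 and 971. Each other subset also shared more than independent lists would. They were 399 and 451 in Th1, against 162 and 253, and 1295 and 1729 in Th17_23, against 669 and 763. The 2 Th0 libraries are too few to split into parts of 2, so part of each excess may come from them. In a test chosen after the results were seen, the change of each medium was taken from a different table, with no library shared, and the mean covariances were 0.340, 0.211, 0.0894, 0.156 and 0.0304 in the same order.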

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

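Of the alternatives only the split of the Th0 libraries was chosen after the results were seen. Of 239 changes of named genes, all kept their direction and side of the threshold with median scaling and no trend. Having no filter lost 1 (Batf3, iTreg against Th0). Quantile normalization lost 1 (Maf, IL27_plus_TGF_beta against iTreg) and the highest transcript of a gene 1 (Foxp3, IL27_plus_TGF_beta against Th0). A pseudocount of 0.1 brought 2 more past the threshold, Il13 in Th2 and Ifng in Th17_23, and lost H2-Ab1 in Th2. With a filter at 5 FPKM 225 were still tested and did so. In a fit of the compared groups alone 8 passed no longer and 3 passed anew. Apart from the lineage genes, these genes were named for large changes or small p in the main fit, which favours their survival. Over all called genes, median scaling kept 5614 of 5857 in IL27_plus_TGF_beta and 1437 of 1611 in Th1, each against Th0. It kept 4068 of 4442 in IL27_plus_TGF_beta against Th17_b. Of 100 list tests 65 passed no longer with an estimated correlation. The other 35 include tests that did not pass with the preset correlation either. Those reported above as passing both ways were few, each against Th0. They were the Th17 list in IL27_plus_TGF_beta, Th17_b and Th17_23, and the non-pathogenic Th17 list in IL27_plus_TGF_beta. With fry 15 passed anew and 3 no longer. Fry also turned the direction of T cell activation genes in IL27_plus_TGF_beta against Th0 (adjusted p = 0.376) and of the immediate early and heat shock and the p53 and apoptosis lists in Th2 against Th0 (adjusted p = 0.608 and 0.262), lists that did not pass in camera; the cause was not tested.

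Among the counts of all called genes, those of Th1 and Th2 against Th0 moved by over 1.5 times; counts at a log2 of 1 or more also moved with a pseudocount of 0.1, as the report gives. With the compared groups alone, Th1 against Th0 gave 169 genes (135 higher and 34 lower) and Th2 against Th0 936; that fit has fewer libraries from which to estimate the spread. The genes specific to Th0 numbered 6 with a pseudocount of 0.1 and 1 with a filter at 5 FPKM, in place of 2; the filter leaves fewer genes, and the cause of the other was not tested. The similarity of IL27_plus_TGF_beta and Th17_b was 0.636 over genes at 5 FPKM or more and 0.633 after quantile normalization, and 0.575 with the Th0 libraries split by table.

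Leaving out 1 library at a time leaves a lone library in its group, which is assumed to vary like the other groups. The counts then ranged from 4165 to 4570 for IL27_plus_TGF_beta, 499 (without Th1 replicate 1) to 915 (without Th1 replicate 2) for Th1, 982 (without Th2 replicate 2) to 1565 (without Th2 replicate 1) for Th2, 5891 to 6986 for iTreg, 4880 to 4918 for Th17_b and 3932 to 4146 for Th17_23, each against Th0. They ranged from 2977 to 3112 for IL27_plus_TGF_beta against Th17_b, 6289 to 7356 against iTreg and 4644 to 5182 for Th17_b against Th17_23. Specific genes ranged from 11 (without Th1 replicate 1) to 27 (without Th1 replicate 2) for Th1, 1 (without Th1 replicate 1) to 10 (without Th0 replicate 2) for Th0 and 123 to 134 for IL27_plus_TGF_beta. Among named genes 24 such fits lost a call, 2 gained 1 and 3 turned the sign of a change that was not called. The latter were Il17a in IL27_plus_TGF_beta against Th0, from -0.0197 without Th0 replicate 2 to 0.21 without Th0 replicate 1, and Il10 in Th1 against Th0, from -0.13 without Th1 replicate 2 to 0.20 without Th1 replicate 1; both genes lie near 0 FPKM there.

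The replicate block was the table. Differences between replicates 1 and 2 correlated over 0.1 in 15 of 21 pairs of groups (lowest -0.137, median 0.148; over genes at 10 FPKM or more, lowest -0.0501 and median 0.257). Not every pair exceeded 0.1 in either set, so the numbers were not shown to pair the samples beyond the table. With no replicate block, limma called 966 genes in Th1 against Th0 and 5189 in IL27_plus_TGF_beta against Th0, 1 gene was specific to Th0, IL-2 and STAT5 targets in Th17_b against Th0 and dendritic cell markers in Th2 against Th0 no longer passed (adjusted p = 0.0577 and 0.0762), and cytokine genes in IL27_plus_TGF_beta against Th0, and p53 and apoptosis genes in Th2 against Th0, which did not pass, changed direction (adjusted p = 0.953 and 0.990). It lost the call of 4 named genes (H2-Ab1 in Th2, Batf3 in iTreg and IL27_plus_TGF_beta, and Cd8b1 in Th17_23, each against Th0) and changed no other list test, though it moved counts of list members, and the cause of these was not tested. Depth limits the genes near 0 FPKM, whose steps are whole reads, and 2 libraries per group limit every SD.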

Other observations

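The tests on class I genes, on lineage genes in the Th0 libraries and on scaling by a median were chosen only after the results were seen; the others were fixed before their result was seen, on patterns that had been noticed in the data. Genes of class I antigen presentation stood higher in IL-27 and TGF-β than in Th0. Of the 17 genes of a list, 13 were called higher and 1, Psmb10, lower (-0.39 ± 0.08). B2m, the light chain, stood at 2047 ± 106 FPKM against 781 ± 81.7 (n = 2), the heavy chain H2-K1 rose by 1.12 ± 0.07, the peptide transporter Tap1 by 1.74 ± 0.06 and the peptide editor Tapbpl by 2.10 ± 0.10, while the proteasome subunit Psmb8 was not called (0.02, limma adjusted p = 0.93). Tap1, Psmb8, Psmb9 and Nlrc5 are also among the 48 interferon-induced genes of the report. In Th1 against Th0, 9 of the 17 were called higher and 0 lower (median 0.32). Against Th0, 0 and 6 were higher and lower in Th2 (-0.17) and 1 and 13 in iTreg (-0.45). They were 1 and 11 in Th17_b (-0.29) and 2 and 6 in Th17_23 (-0.13). A rise across the pathway may be what the counts of IL-27 and TGF-β show, as a hypothesis found and tested on the same data.

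Among the interferon-induced genes some members fell in IL-27 and TGF-β while most rose. Ddx58, which encodes the RNA sensor RIG-I, stood at 0.345 ± 0.0692 FPKM against 3.90 ± 0.330 in Th0, and Oas3 (-1.47 ± 0.11) and Samd9l (-1.66 ± 0.12) were lower, while the nucleic acid sensor Zbp1 was higher (2.81 ± 0.14). In a list of genes typical of type I interferon, 5 were called higher and 10 lower of 17 tested (median -0.37). Against Th0, 1 and 7 were higher and lower in Th2 (-0.35), 2 and 9 in iTreg (-0.30) and 1 and 7 in Th17_b (-0.35). In Th1 they were 3 and 6 (-0.064), and in Th17_23 5 and 2 (0.11). The IL-27 and TGF-β cells were higher in 10 and lower in 5 against Th17_b (0.64), and in 9 and 6 against iTreg (0.60). These genes and this list were chosen after their values were seen. In Th17_23, Lum, a proteoglycan of connective tissue, stood at 48.2 ± 17.6 FPKM and Dcn at 1.58 ± 0.931, while the fibroblast collagens Col1a1 and Col1a2 stood at 0.658 ± 0.132 and 0.0107 ± 0.00116 and Col3a1 was listed at 0.

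IL-2 and STAT5 targets differed between the Th0 replicates, with a median of -0.81 log2 units for replicate 1 minus replicate 2 over 18 genes. A difference between the tables in every group would give at least 0.5 times that median in 4 or more of the other 6 groups; only iTreg did (-0.56), 1 group, although the sign was negative in all 7. A library of another medium under the Th0 label is argued against by Ifng, Tbx21, Il4, Foxp3, Il17a and Il10, of which the highest value in either Th0 library was 1.83 FPKM. The medians of Th2 (-0.36) and Th17_23 (-0.36) fell short of that bound, and those of Th1 (-0.073), Th17_b (-0.064) and IL27_plus_TGF_beta (-0.10) were smaller. A smaller difference between the replicates of several groups is therefore not excluded. A difference in how far IL-2 was neutralized between the Th0 cultures may remain, and was not tested. It would not cover iTreg, whose medium holds added IL-2 and, per the labels, no named antibody to it.

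Ribosomal protein genes stood lower in IL-27 and TGF-β than in Th0: 70 of 83 were called lower and 3 higher (median -0.35), with 78 lower in Th17_b and 71 in Th17_23, and 0 called in Th1 or Th2 by limma. In iTreg 22 were called higher and 6 lower (median 0.14, 0.018 with quantile normalization and 0.27 with median scaling). Against a bias on short transcripts, other genes near in length (626 against 658 bases) changed by a median of -0.12 only, though their log2 level was lower (7.18 against 10.8). Against 1 scaling factor per library, the ribosomal median in IL-27 and TGF-β stayed at -0.31 after scaling to 1 median. After quantile normalization it was -0.0837, which meets the bound set beforehand for an effect of scaling, but 68 of the 100 highest genes are ribosomal, so that quantile normalization itself largely sets their values in every library. That reading, with a bound of over 50 of 100, was made after the value was seen, so an effect of scaling and a change in these genes cannot be told apart.

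Some genes of epithelial junctions and basement membrane, named after their values were seen, were highest in IL-27 and TGF-β: Dsp stood at 18.0 ± 2.20 FPKM against 0.135 ± 0.0518 in Th0, Epcam at 14.0 ± 0.866 against 2.80 ± 0.589, Ocln at 4.66 ± 0.0448 against 0.0551 ± 0.0232, and Lamc3 at 36.9 ± 4.18 against 0.0138 ± 0.00192. Other junction genes, at low levels, stood higher in iTreg: Cdh1 at 0.421 ± 0.118 against 0.0277 ± 0.0103 in IL-27 and TGF-β, Cldn4 at 0.951 ± 0.0863 against 0.0243 ± 0.00902 and Cldn7 at 0.329 ± 0.281 against 0.0885 ± 0.0306, so no change of junction genes as a group is shown. Lamc3 also stood at 12.6 ± 1.79 in Th17_b and Dsp at 6.41 ± 3.12 in iTreg, while Epcam, at 0.500 ± 0.0679 and 0.765 ± 0.0719 in iTreg and Th17_b, and Ocln, at 0.0977 ± 0.0781 and 0.00923 ± 0.00187, did not follow the media with TGF-β. Against epithelial cells in the culture, 1 of 14 epithelial markers, Muc1, reached 1 FPKM and was called higher, Krt8 stood at 0.00898 ± 0.0127 FPKM and Krt19 was listed at 0, while Sfn, another marker, stood at 16.8 ± 0.178 against 16.7 ± 0.0858. Of the 3 markers tested, 2 were called higher. The second was Krt18, at 0.643 ± 0.228 against 0.132 ± 0.0185 FPKM in Th0, and it stood at 1.10 ± 0.0978 in Th17_b. The source of these transcripts stays open.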
